A study of Rhodopseudomonas palustris with 2 samples.

How the data were processed

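RNA sequencing libraries were made from total RNA of a purple photosynthetic bacterium labelled Rhodopseudomonas palustris, 1 from an untreated culture and 1 from a culture treated with alpha-rhamnetin-3-rhamnose (ARR), a methylated flavonol joined to the sugar rhamnose. Per the labels' protocols, both cultures were grown for 72 hours at 37 degrees Celsius under 2500 lux of light, RNA was extracted with TRIzol and treated with DNase, and the libraries were sequenced on an Illumina HiSeq2000. Removal of ribosomal RNA is not given in the sources used here. The groups were taken from the treatment given in the labels.

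Per the file headers, the authors assembled the reads of each library and of both libraries together without a reference genome, and the joint assembly holds 10963 assembled sequences (unigenes). The assembler, the read mapper, the counter and the authors' test are not given in the sources used here. The authors deposited raw counts of fragments per unigene, with totals of 5861355 for the control and 5725798 for the treated library. The deposited FPKM values equal fragments divided by unigene length and by the library total, with a largest difference of 5e-05. The deposited read counts from the mapping tables are split into reads mapped at 1 place and reads mapped at several places, and the same tables give the depth as a coverage signal. Of the mapped reads, 24.5% in the control and 26.7% in the treated library were mapped at several places. For 99.1% of the unigenes in each library, the deposited fragments lay between the number of reads mapped at 1 place and that number divided by 2, so that reads mapped at several places were taken as left out of the fragments. The authors' deposited table of differences gives, per the file headers, the log2 ratio of treated over control FPKM, a p-value and a false discovery rate for 3360 unigenes. Those p-values compare 2 libraries, not 2 conditions. The deposited match tables give the alignment score, the expectation value and the identity of each match, as a fraction in the protein (Nr) and nucleotide (Nt) tables and as a percent in the KEGG table, per the file headers.

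Each unigene was assigned to the genus of its first listed protein match. The analysis was fixed on the genus Rhodopseudomonas provided that it took at least 50% of the fragments on matched unigenes in both libraries. It took 76.9% in the control and 83.5% in the treated library. The deposited counts of Rhodopseudomonas unigenes with at least 10 fragments over both libraries were scaled by the trimmed mean of M values (edgeR 4.0.16, in R 4.3.3) computed on those unigenes. The log2 ratio of treated over control was taken after adding 0.5 fragments. Its 95% interval is the exact conditional binomial interval and, like the exact Clopper-Pearson interval of each share, covers counting error only. A count of 0 allows a share of up to 5.12e-05% of the control and 5.24e-05% of the treated fragments (3 counts). With 1 library per group the spread between cultures is unknown, so that no test between conditions, no p-value and no count of significant genes was computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

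The first listed nucleotide match of a unigene is given with the strain and the positions in that strain's genome sequence as the deposited match table lists them. The median identity of the Rhodopseudomonas unigenes to their nucleotide match was 86%, so these are positions in related genomes, not in the genome of the cultured strain. The best protein match spanned a median of 59.1% of a unigene. Of the 1367 Rhodopseudomonas unigenes, 587 were spanned under 50%, and these held 90.2% of the fragments on Rhodopseudomonas unigenes. A unigene named after its match can therefore hold neighbouring genes as well, and its value belongs to the whole unigene. The library type is not given, so that overlapping and antisense transcripts cannot be told from each other.

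30 gene lists were fixed before the data were examined and matched on the description of the best protein match. A list can therefore include unigenes of other functions whose descriptions carry its words, and miss genes that lie in a unigene named after another gene. A list with at least 5 unigenes was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called beyond the random lists under percentile 2.5 or over percentile 97.5. The lists without a Rhodopseudomonas unigene were the photosynthetic apparatus, glutathione S-transferases, and stress and stationary phase. Named unigenes were chosen by a rule fixed before the data were examined. It takes the 10 highest and the 10 lowest log2 ratios among unigenes with at least 100 fragments, at least 300 bases, an informative description and 1 sign under every scaling. Of the unigenes that meet this, 1 is kept per description, the one with most fragments. It adds the 2 most abundant, the highest and the lowest unigene of each list, and the 10 Rhodopseudomonas unigenes with most fragments. It named 110 unigenes. Unigenes named outside this rule are marked as chosen after their values were seen.

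The steps were tested on simulated data for the 1330 analysed unigenes of this comparison. Simulated log2 ratios of 1 and 2 were recovered with medians of 1.01 and 2.00, and those of -1 and -2 with medians of -1.00 and -1.99, among unigenes with at least 100 fragments. Of 100 simulated lists of 15 unigenes with no shift, 3 lay beyond the random lists, and of 100 lists with a shift of 0.5 on the log2 scale, 68 did. Their members were drawn at random, so these counts do not describe lists whose unigenes share an assembly cluster or reads. The alternatives fixed beforehand were other scalings (library total, analysed total, and the median of ratios as in DESeq2 1.42.0), minimums of 1, 50 and 200 fragments, 5 fragments added, all matched unigenes, counts summed per best match, a length of at least 500 bases, deposited FPKM with 1 added, a 4-fold threshold, KEGG descriptions, summed lists, and other rules for the genus. Reads mapped at several places included, unigenes with no sibling in the assembly, unigenes spanned at least 50% by their match, unigenes whose nucleotide match is also Rhodopseudomonas, and ratios within 3 other genera were added after seeing the data. Deposited gene ontology and COG tables were not used.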

Results

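The data comprised 2 RNA sequencing libraries of Rhodopseudomonas palustris cultures, 1 untreated control and 1 treated with alpha-rhamnetin-3-rhamnose (ARR). The study asked how the bacterium responds to this flavonol glycoside and how it may transform it. The control library held 14739916 mapped reads, 11131738 of them mapped at 1 place, with fragments counted on 10314 unigenes. The treated library held 14962547 mapped reads, 10962982 of them at 1 place, with fragments counted on 10299 unigenes. There were no replicates, so every difference below is a difference between these 2 libraries, and every interval covers counting error only. The control reads alone had been assembled into 9725 unigenes with an N50 of 1885 bases and a GC content of 60.7%. The treated reads alone gave 7341 unigenes with an N50 of 2134 bases and a GC content of 61.2%.

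The first comparison was of the organisms that the unigenes matched. Rhodopseudomonas took most fragments in both libraries, and the share of unigenes matching other bacteria differed between them. Unigenes matching Rhodovulum, another genus of purple bacteria, and Clostridium, a genus of anaerobic spore formers, took smaller shares of the treated library. Those matching Massilia, a genus of soil and water bacteria, took a larger share of it. The best protein matches named 431 genera in all.

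Rhodopseudomonas unigenes, 1367 in number, took 70.2% of the control fragments (95% Clopper-Pearson interval 70.16 to 70.23) and 76.2% of the treated fragments (76.14 to 76.21). The best match of 851 of them lay in the sequenced strain BisA53. Rhodovulum unigenes, 2204 in number, took 3.64% of the control and 0.993% of the treated fragments, a ratio of 0.273 (95% interval 0.270 to 0.275). Clostridium unigenes, 2424 in number, took 3.23% and 1.95%, a ratio of 0.604 (0.599 to 0.608). Eubacterium unigenes went from 1.41% in the control to 0.714% in the treated library, and unigenes matching unnamed Lachnospiraceae from 0.911% to 0.448%. Most of either share lay on 1 unigene. CL85.Contig2_All, whose nucleotide match is a ribonuclease P RNA, held 80232 of the 82816 control and 38878 of the 40874 treated Eubacterium fragments, and the share ratio of the other 78 unigenes was 0.791. Unigene2785_All held 49383 of the 53399 control and 23327 of the 25656 treated Lachnospiraceae fragments, and the share ratio of the others was 0.594. Massilia unigenes, 755 in number, took 0.0355% of the control and 0.681% of the treated fragments, 19.2 times as large a share. Bradyrhizobium, a close relative of Rhodopseudomonas, took 3.29% and 3.03%. Of its fragments CL173.Contig2_All, whose nucleotide match is to the Rhodopseudomonas palustris DX-1 genome, held 69.0% in the control and 64.8% in the treated library. The other 186 Bradyrhizobium unigenes together had a share ratio of 1.05, while over the 175 with at least 10 fragments the median log2 ratio by library total was -1.32, with 82.3% below 0. Unigenes with no protein match took 8.68% and 8.76%. The 2 most abundant unigenes of all, Unigene369_All with 197302 control and 164203 treated fragments and CL55.Contig1_All with 115557 and 145893, had no protein match and a nucleotide match in Clostridium saccharolyticum. These and CL85.Contig2_All, Unigene2785_All and CL173.Contig2_All were chosen after their values were seen. Unigenes matching ribosomal RNA took 0.176% of the control and 0.191% of the treated fragments.

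**Figure D1:**
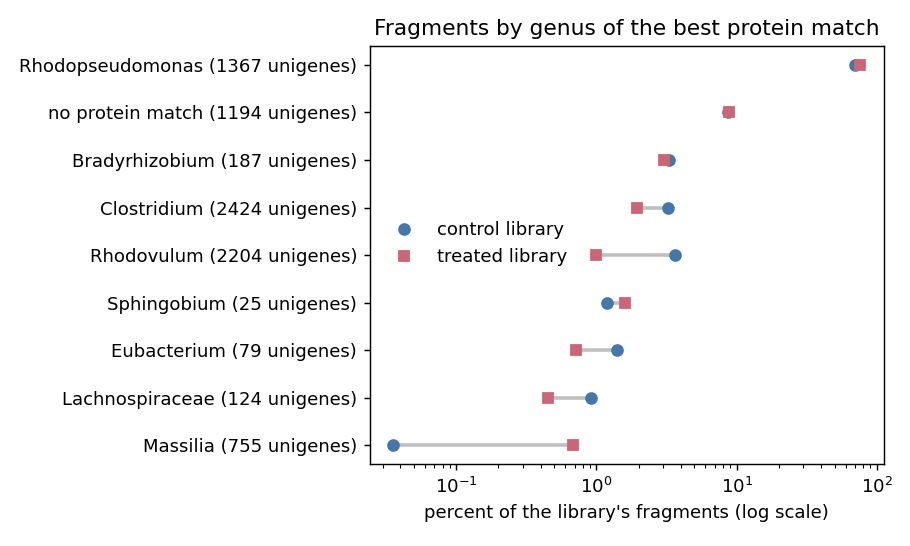
Percent of each library's fragments (log axis) on unigenes whose best protein match lies in the named genus, for the control (circles) and treated (squares) library, with the number of unigenes in brackets. Rhodopseudomonas lay at 70.2% and 76.2%, Rhodovulum at 3.64% and 0.993%, and Massilia at 0.0355% and 0.681%.

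The GC content of these groups differed. The median was 65.0% over Rhodopseudomonas unigenes, 69.0% over Rhodovulum unigenes and 46.6% over Clostridium unigenes. Light-harvesting proteins, which gather light for the photosynthetic reaction centre, named several Rhodovulum unigenes and no Rhodopseudomonas unigene. The most abundant of them, CL157.Contig1_All, held 15698 control and 4212 treated fragments, a log2 ratio of -1.86 relative to the library totals, close to the median of -1.82 over 2029 Rhodovulum unigenes with at least 10 fragments. CL157.Contig2_All (-2.31), Unigene514_All (-2.53) and Unigene3015_All (-2.36), also light-harvesting proteins, lay lower. These values are not scaled within the genus, and these unigenes were chosen after their values were seen. A unigene is named by its best protein match alone, so Rhodopseudomonas unigenes named after another gene can hold light-harvesting genes. The chlorophyllide reductase unigene CL306.Contig1_All, for example, was spanned 11.2% by its protein match, and its nucleotide match was to reaction centre genes.

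The second comparison was the authors' own. The authors' deposited table listed mostly unigenes of other genera, and the direction went with the genus. Of its 3360 unigenes, 922 were higher and 2438 lower in the treated library. In the authors' deposited table, 1011 unigenes matched Rhodovulum, of which 990 were lower. A further 603 matched Clostridium, of which 462 were lower, and 509 matched Massilia, of which 479 were higher. Rhodopseudomonas accounted for 185 of the listed unigenes, 82 higher and 103 lower, so that 94.5% of the authors' deposited table lay outside the genus. That includes 231 unigenes with no protein match. Most of the assembly lies outside the genus as well, since 1367 of its 10963 unigenes matched Rhodopseudomonas. The table listed 13.5% of the Rhodopseudomonas, 45.9% of the Rhodovulum, 24.9% of the Clostridium and 67.4% of the Massilia unigenes. All 3360 had the same sign as the ratio of fragments scaled by the library totals. That follows from the definition of FPKM, since unigene length cancels in the ratio, and is no separate support. In 569 of them 1 library held no fragment, and the authors' deposited log2 ratios reach -15.09 and 16.79 there, which are set by the small value put in place of 0 and measure no fold.

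**Figure D2:**
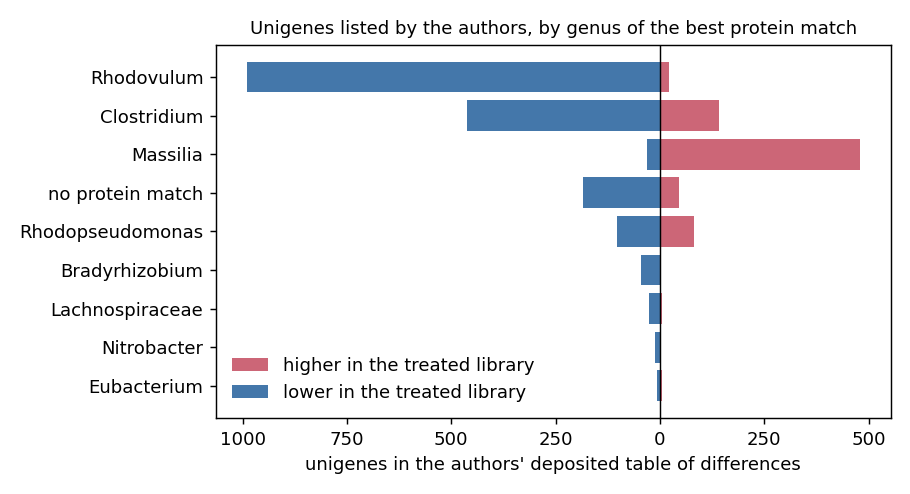
Number of unigenes in the authors' deposited table of differences, to the right those higher and to the left those lower in the treated library, by genus of the best protein match. Rhodovulum has 990 of its 1011 to the left and Massilia 479 of its 509 to the right, and Rhodopseudomonas has 82 to the right and 103 to the left.

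The third comparison was of Rhodopseudomonas unigenes with one another, scaled within the genus. The isocitrate lyase unigene of the glyoxylate bypass was 4.16-fold higher in the treated library, cysteine synthase A 4.76-fold, a diguanylate cyclase/phosphodiesterase unigene 4.65-fold and cystathionine beta-synthase 13.7-fold. The main catalase/peroxidase unigene had a log2 ratio of 1.10. The anaerobic cyclase unigene of bacteriochlorophyll synthesis lay near 0, at 0.06. A permease unigene, at -2.94, an acyl-CoA dehydrogenase unigene, at -2.20, and a short unigene of ribosomal protein S1, at -2.06, were among the lowest. Of 1330 analysed unigenes, 112 were at least 2-fold higher and 175 at least 2-fold lower in the treated library, and 1043 (78.4%) lay within 2-fold. The median log2 ratio was -0.04, with quartiles of -0.52 and 0.40.

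The count of 2-fold unigenes rested in part on low counts. Of the 287 unigenes beyond 2-fold, 147 had under 100 fragments over both libraries, and the counting interval of 252 excluded 0. With a minimum of 200 fragments, 57 unigenes were higher and 56 lower. Scaling by the analysed fragments moved the median of all unigenes by -0.13 on the log2 scale and gave 89 higher and 202 lower, and requiring 500 bases gave 69 and 75. Unigenes at least 2-fold lower had a median length of 370 bases and a median GC content of 66.6%, against 1975 bases and 64.9% for those within 2-fold. The best nucleotide match was also Rhodopseudomonas for 65.7% of the lower unigenes, 93.8% of the higher unigenes and 95.8% of those within 2-fold. Fragments per kilobase had medians of 126 for the lower unigenes, 613 within 2-fold and 110 for Rhodovulum unigenes, whose median length was 333 bases. Whether some of the lower unigenes belong to an organism whose share fell was not tested.

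Isocitrate lyase, the first enzyme of the glyoxylate bypass, named Unigene2819_All, which held 9193 control and 37117 treated fragments. The log2 ratio was 2.06 (95% interval 2.02 to 2.09), or 4.16-fold. The protein match spanned 22.9% of the 7121 bases of this unigene. The nucleotide match lay at positions 4949385 to 4951256 of the DX-1 genome, with 90% identity. 2-Methylcitrate dehydratase, of the route that breaks down propionate, named Unigene1904_All with 93 and 488 fragments and a log2 ratio of 2.43 (2.11 to 2.77). Its nucleotide match lay at 2870982 to 2869610 of the TIE-1 genome. Methylcitrate synthase, Unigene1927_All, had 43 and 117 fragments and a log2 ratio of 1.48. It was chosen after its values were seen. Acetyl-CoA acetyltransferase, which joins or splits acetyl units, named Unigene1317_All with 31993 and 61010 fragments and a log2 ratio of 0.97 (0.95 to 0.99), at 4281727 to 4282897 of the BisA53 genome.

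The cystathionine beta-synthase unigene, Unigene295_All, had a log2 ratio of 3.78 (3.37 to 4.24), from 49 to 658 fragments, with its match at 228205 to 227789 of segment 8 of the CGA009 genome. Cysteine synthase A, Unigene1284_All, had 1313 and 6071 fragments and a log2 ratio of 2.25 (2.17 to 2.34), at 4045713 to 4046687 of the BisA53 genome. Flavocytochrome c sulfide dehydrogenase, which oxidises sulfide, named Unigene1871_All with 817 and 3565 fragments and a log2 ratio of 2.17 (2.06 to 2.28). The diguanylate cyclase/phosphodiesterase unigene CL47.Contig2_All, named after enzymes of the messenger cyclic di-GMP, had 10023 and 45249 fragments and a log2 ratio of 2.22 (2.19 to 2.25). A unigene named after the enzyme that adenylylates glutamine synthetase, CL120.Contig1_All, had 8130 and 31657 fragments and was 4.01-fold higher, with a log2 interval of 1.97 to 2.04. Serine hydroxymethyltransferase, Unigene319_All, stood at 1.86 with 354 and 1249 fragments, while another unigene of that name, CL7.Contig2_All, stood at -0.02 with 8969 and 8615.

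At the other end, the permease unigene Unigene1569_All had 1141 and 144 fragments and a log2 ratio of -2.94 (-3.20 to -2.69), at 184556 to 185645 of segment 12 of the CGA009 genome. The acyl-CoA dehydrogenase unigene Unigene3002_All, of fatty acid breakdown, had 2033 and 429 fragments and a log2 ratio of -2.20 (-2.36 to -2.05). The DEAD/DEAH box helicase unigene CL272.Contig1_All had 4981 and 1267 fragments and a log2 ratio of -1.93, and the drug resistance transporter unigene Unigene52_All 429 and 114 fragments and -1.87. A TetR family regulator, Unigene2894_All, stood at -1.65 with 3620 and 1122 fragments. Its protein match had 66% identity, and its nucleotide match, over 79 bases, lay in Agromonas. The iron-related sigma factor unigene Unigene2092_All stood at -1.16 with 5162 and 2249.

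Of the 30 gene lists, 23 held at least 5 Rhodopseudomonas unigenes, and 3 of these lay beyond the matched random lists. By chance 1.15 would, if the unigenes of a list moved independently, which assembly siblings within a list may not. The 3 lists were flagella and chemotaxis (higher), ribosomal proteins (lower) and the tricarboxylic acid cycle (lower). Flagella and chemotaxis, 49 unigenes, had a median of 0.17 at percentile 97.6, with 8 members at least 2-fold higher and 6 at least 2-fold lower. The chemotaxis sensory transducer CL4.Contig8_All stood at 2.37 with 384 and 1927 fragments. The flagellin unigenes went both ways, CL184.Contig1_All at -0.59 with 57854 and 37359 fragments and CL184.Contig3_All at 0.57 with 21868 and 31620. Summed over the list the log2 ratio was 0.03, and fragments summed per best match gave a median of -0.04 at percentile 55.8.

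The ribosomal protein list held 6 unigenes with a median of -1.64 at percentile 0.05. It misses any ribosomal protein gene that lies in a unigene named after another gene, so it does not describe ribosomal proteins as a whole. Its most abundant member, the S1 unigene CL203.Contig2_All, stood at -0.03 with 10213 and 9692 fragments, and the list summed to -0.27. The L13 unigene CL268.Contig2_All stood at -1.64 with 2452 and 766 fragments. The S4, S18 and S3 unigenes held only 107 and 33, 28 and 7, and 11 and 8 fragments, and were chosen after their values were seen. Over all matched unigenes of every genus the list had 263 members and a median of 1.08, the other sign. That scaling moved the Rhodopseudomonas unigenes by a median of 0.75 and took in genera whose shares differed, so the signs are not comparable.

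The tricarboxylic acid cycle list, 10 unigenes, had a median of -0.42 at percentile 2.12, while its summed fragments gave 0.93, the other sign. The isocitrate lyase unigene, of the glyoxylate bypass, held 55.4% of those fragments. The list's words also took in methylcitrate synthase and homocitrate synthase unigenes. Its median and sum therefore do not describe the cycle enzymes alone. The 2-oxoglutarate dehydrogenase unigene CL140.Contig4_All stood at 0.61, the fumarate hydratase unigene CL273.Contig2_All at -1.02 and the aconitate hydratase unigene CL267.Contig3_All at -2.24. CL273.Contig2_All was chosen after its values were seen. With reads mapped at several places included, an alternative chosen after seeing the data, the list median was 0.70 at percentile 99.8 and CL267.Contig3_All stood at 0.92. The direction of this list therefore differed with how shared reads were counted.

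The oxidative stress list, 10 unigenes, had a median of -0.06 at percentile 46.9, with 3 members at least 2-fold higher and 3 at least 2-fold lower. Its main members, the catalase/peroxidase unigene CL65.Contig4_All, which removes hydrogen peroxide, and the iron store bacterioferritin, Unigene1469_All, stood at 1.10 (1.07 to 1.12) and 0.98 (0.94 to 1.02). Summed over the list the log2 ratio was 0.88, again of the other sign than the median. Short unigenes with the same or a related catalase match stood at 4.76 (CL65.Contig2_All, 17 and 459 fragments) and -1.91 (CL65.Contig3_All, 1061 and 273 fragments). The direction of the list differed with the unigenes and reads counted. With a minimum of 200 fragments the median was 0.49 at percentile 98.6. Over all mapped reads it was -0.47 at percentile 3.36, and over unigenes spanned at least 50% by their match it was -1.01 at percentile 0.5. These last 2 alternatives were chosen after seeing the data.

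The bacteriochlorophyll and carotenoid list, 10 unigenes of pigment synthesis, had a median of 0.16 at percentile 73.1 and summed to -0.18. The anaerobic cyclase unigene Unigene2884_All stood at 0.06 with 70174 and 71249 fragments, a value that scaling by the analysed fragments turned to -0.06. The magnesium chelatase unigene CL240.Contig2_All stood at -0.16. The chlorophyllide reductase unigene CL306.Contig1_All stood at -1.32 with 44378 and 17271 fragments, and its nucleotide match, with 98% identity, was to the reaction centre genes pufL and pufM of a Rhodoplanes strain. The nitrogen fixation list, 10 unigenes, had a median of -0.50 at percentile 11.3, with NifE (Unigene1864_All) at -0.75, the nitrogenase alpha chain (Unigene394_All) at -0.87 and NifA (Unigene1782_All), the regulator of the nitrogenase genes, at 0.00. Unigene1864_All was chosen after its values were seen. The list also took in the hydrogenase maturation unigene HypF (Unigene1553_All), at -0.57 with 3636 and 2371 fragments. The search for nif gene names, made without regard to case, also matches NiFe. With a minimum of 50 fragments, which keeps this unigene, the list median was -0.69 at percentile 1.38. The 3 unigenes of the list for the Calvin cycle, which fixes carbon dioxide, stood between 0.11 and 0.90. Transketolase, CL345.Contig1_All, an enzyme shared with other routes, was the highest, with 5940 and 10799 fragments. Ribulose bisphosphate carboxylase, CL116.Contig1_All, chosen after its values were seen, stood at 0.66. A RuBisCO-like protein, Unigene2410_All, which is not the carbon dioxide fixing enzyme itself, was the lowest.

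Of the lists chosen for the compound itself, those with at least 5 unigenes lay within the random lists. Matched on words, they also held unigenes of other functions, so they do not settle how enzymes acting on the compound moved. Aromatic ring degradation took in 4-hydroxybenzoate polyprenyltransferase and 2-polyprenylphenol 6-hydroxylase. Multidrug efflux took in heavy metal pumps and auxin carriers, and small-molecule methyltransferases took in hydroxymethyltransferases. Aromatic ring degradation, 9 unigenes, had a median of -0.10 at percentile 30.6, and the feruloyl-CoA synthase unigene Unigene1879_All stood at 0.12 with 19190 and 20304 fragments. Glycoside hydrolases, enzymes that split sugars from other groups, numbered 5 with a median of 0.23 at percentile 84.0. Of these, CL40.Contig1_All stood at 1.56 with 2143 and 6124 fragments. The alpha amylase unigene Unigene1307_All stood at -1.49, and its nucleotide match lay in Ralstonia eutropha. Small-molecule methyltransferases, 15 unigenes, had a median of -0.02 at percentile 50.6, and glycosyltransferases, 7 unigenes, a median of 0.16 at percentile 74.2. Multidrug efflux, 16 unigenes, had a median of 0.02 at percentile 76.5 and summed to 0.46, with the efflux unigene Unigene6_All at 1.67 and 646 and 1994 fragments. Aldehyde and alcohol dehydrogenases, 10 unigenes, had a median of -0.14 at percentile 22.2, while the alcohol dehydrogenase unigene Unigene1640_All stood at 1.11 with 1647 and 3452 fragments. The single rhamnose and nucleotide-sugar unigene, the UDP-glucose dehydrogenase Unigene2189_All, stood at -0.25. The 4 monooxygenase unigenes had a median of 0.01.

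**Figure D3:**
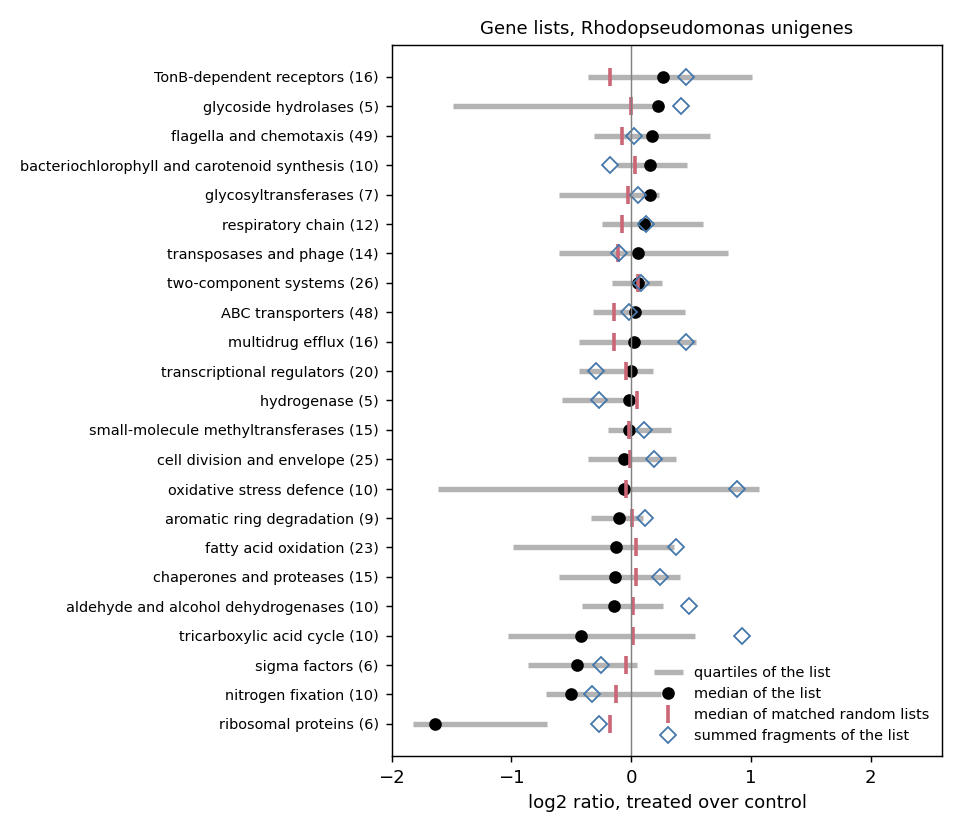
Log2 ratio of treated over control for the 23 gene lists with at least 5 Rhodopseudomonas unigenes (number in brackets), as the median (filled circle) with quartiles (grey bar), the median of matched random lists (tick) and the ratio of summed fragments (diamond). The ribosomal protein median lies at -1.64. The tricarboxylic acid cycle list, which includes isocitrate lyase, lies at -0.42 by its median and at 0.93 by its sum.

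Of the other lists, TonB-dependent receptors, which take up iron complexes, had a median of 0.27 at percentile 96.8 over 16 unigenes, with the siderophore receptor unigene CL324.Contig1_All at 1.27. ABC transporters, 48 unigenes, stood at 0.03 (percentile 92.9), the respiratory chain, 12 unigenes, at 0.11 (82.1) and two-component systems, 26 unigenes, at 0.06 (50.5). Transcriptional regulators, 20 unigenes, stood at 0.00 (61.0), sigma factors, 6 unigenes, at -0.45 (8.95) and hydrogenase, 5 unigenes, at -0.01 (29.5). Chaperones and proteases, 15 unigenes, stood at -0.14 (13.6), with the chaperonin GroEL unigene CL125.Contig2_All at 0.54 and 82949 and 117429 fragments. Fatty acid oxidation, 23 unigenes, stood at -0.12 (14.6), cell division and envelope, 25 unigenes, at -0.06 (37.1) and transposases and phage, 14 unigenes, at 0.06 (78.9). The summed fragments had the other sign than the median for fatty acid oxidation (0.38), chaperones and proteases (0.24), cell division and envelope (0.19), aldehyde and alcohol dehydrogenases (0.48), aromatic ring degradation (0.12) and small-molecule methyltransferases (0.11). The same held for transcriptional regulators (-0.29), transposases and phage (-0.10) and ABC transporters (-0.02). The 2 unigenes of the ATP synthase list, both of the flagellum-specific enzyme, stood at -0.04 and -1.14.

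Unigenes that shared a best match did not always move together. Among 68 best matches with at least 2 Rhodopseudomonas unigenes of at least 100 fragments, 7 had members at least 4-fold apart, and in 3 of these 1 member was at least 2-fold higher and another at least 2-fold lower. 2-Isopropylmalate synthase, of leucine synthesis, named CL182.Contig2_All with 1328 and 412 fragments (-1.64) and CL182.Contig3_All with 254 and 929 (1.91). With reads mapped at several places included, the same unigenes held 51305 and 154881 reads (1.64) and 49190 and 155915 reads (1.71). These unigenes were chosen after their values were seen.

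**Figure D4:**
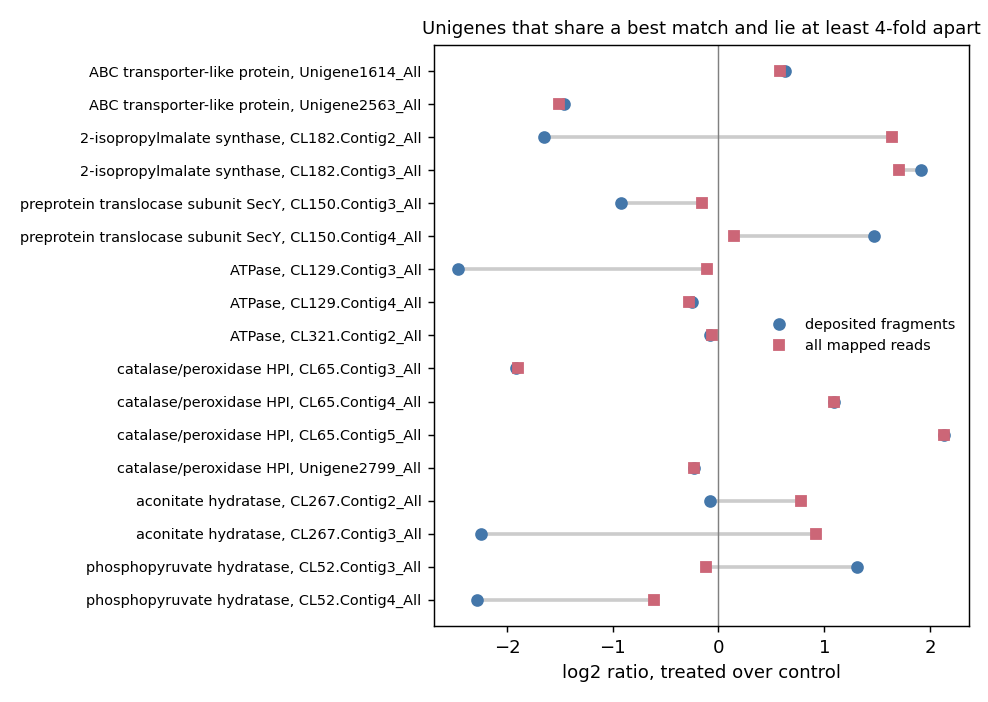
Log2 ratio of treated over control of the unigenes of 7 best matches whose members lie at least 4-fold apart, from the deposited fragments (circles) and from all mapped reads (squares). The 2-isopropylmalate synthase unigenes lie at -1.64 and 1.91 by fragments and at 1.64 and 1.71 by all mapped reads.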

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

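The tests in this part were all chosen after the values they bear on had been seen.

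Unigenes matching Massilia, outside the comparison within Rhodopseudomonas, held 0.681% of the treated fragments, above the 0.0355% of the control, and were listed for that reason. Unigenes matching unnamed Ruminococcaceae, 30 in number, held 0.00917% of the treated fragments, above 0.00353% of the control.

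The authors' deposited table, with 94.5% of its unigenes outside Rhodopseudomonas, is the first pattern. That share includes 231 unigenes with no protein match, and only 1367 of all 10963 unigenes matched the genus. Counting noise is argued against for the Rhodovulum part, since 96.1% of its 2029 unigenes lay below 0 by library total. Misnamed Rhodopseudomonas sequences are argued against for Clostridium by a median GC of 46.6%, outside the 62.1% to 69.1% between the 10th and 90th percentile of Rhodopseudomonas, while the Rhodovulum and Massilia medians (69.0% and 62.9%) lay inside it. For Massilia they are argued against by protein identity, at least 95% in 91.8% of its 610 unigenes against 5.3% of Rhodopseudomonas unigenes. For Rhodovulum this was 9.7%, which does not decide. By library total, 96.1% of the Rhodovulum and 5.7% of the Massilia unigenes lay below 0. In Rhodopseudomonas unigenes drawn to the same classes of fragment count, 61.5% (95% range 59.5% to 63.7%) and 62.2% (58.4% to 65.9%) did. That direction is part of the pattern itself, and the draws take misnamed sequences as a random sample of Rhodopseudomonas, so it does not decide. Misnamed unigenes within these genera are not excluded. The best nucleotide match of 426 of the 2029 Rhodovulum unigenes lay in Rhodopseudomonas, and 96.5% of these 426 were below 0 by library total. For Massilia, these identities and its shares of 0.0355% of the control and 0.681% of the treated fragments go with a change in the mix of organisms between these libraries. For Rhodovulum such a change stays open. Its median lay at or below -1 in 23 of 23 gene lists, and 17.7% of its unigenes 2-fold lower by library total stayed so when scaled on the genus. The shift of the whole genus (upper quartile -1.28) fixes both outcomes, so neither decides. With 1 library per group, an effect of the treatment on that mix was not tested.

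The unigenes of 1 best match that lie at least 4-fold apart are the second pattern. Once reads mapped at several places were included, 2 of the 7 best matches stayed 4-fold apart. Such reads count towards near-identical assembled sequences alike, so they draw the ratios together whether or not the sequences differ. Whether shared reads account for the pattern is therefore not decided. The catalase/peroxidase unigenes stayed apart and span 4.93 points of GC. Rhodopseudomonas unigenes run from 62.1% to 69.1% between their 10th and 90th percentile, so this span does not separate another organism from the spread within 1. The ABC transporter-like unigenes stayed apart as well, and their span of 1.43 points of GC does not separate another organism from a second copy of the gene, so that these cannot be told apart.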

How the results depend on the processing

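No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible either. Alternatives on all mapped reads, siblings, spans and nucleotide matches were chosen after seeing the data, and for results that moved the cause was not tested unless the alternative's own construction shows it. Of the 110 named unigenes, 47 were at least 2-fold apart, and 2 of these changed sign in some setting: CL267.Contig3_All was 0.92 over all mapped reads, and CL65.Contig3_All was 1.03 with fragments summed per best match. Of the 287 unigenes beyond 2-fold, 147 had under 100 fragments, which limits their precision.

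The share of Rhodopseudomonas was 67.6% of the control and 73.5% of the treated fragments with an expectation value of at most 1e-20, 70.9% and 76.9% with any equal best match, and 74.8% and 80.6% by nucleotide match. By nucleotide match the share ratio was 0.821 for Clostridium, or 0.565 without Unigene369_All and CL55.Contig1_All, which have no protein match. It was 29.7 for Massilia, but over only 2 unigenes with 2 control and 58 treated fragments, which settles nothing. With the stricter expectation value it was 0.293 for Rhodovulum and 21.8 for Massilia. At least 500 bases left 2877 control and 2232 treated unigenes. In the authors' deposited table, 760 unigenes were higher and 1549 lower by at least 4-fold.

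Of 1330 unigenes in the main setting, 112 were 2-fold higher and 175 lower. With a minimum of 50 fragments these were 71 and 96 of 1088, and with 200 fragments 57 and 56 of 872. At 500 bases or more they were 69 and 75 of 1008. At 4-fold, 20 were higher and 60 lower, and over all matched unigenes 2155 and 2640. Scaling by the analysed fragments gave 89 and 202.

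Over all matched unigenes, 13 lists lay beyond the random lists, and 1 by KEGG description. Without siblings 0 of 16 lists did, but ribosomal proteins (3 unigenes) and the tricarboxylic acid cycle (4 unigenes) were among the 14 lists under 5 unigenes and were not tested. Scaling over all matched unigenes moved the Rhodopseudomonas unigenes by a median of 0.75, and the lists then hold unigenes of genera whose shares differed, so that signs there are not comparable with those within the genus. The medians over all matched unigenes were -1.30 for bacteriochlorophyll and carotenoid synthesis, -0.20 for flagella and chemotaxis, -0.77 for glycoside hydrolases, 0.15 for oxidative stress defence, -0.95 for the respiratory chain, 1.08 for ribosomal proteins and -0.57 for two-component systems, all of the other sign than within the genus. Of the same sign but now beyond were TonB-dependent receptors at 1.24, hydrogenase at -1.08 and transposases and phage at 0.47.

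Flagella and chemotaxis lay within the random lists at 0.048 scaled by the analysed fragments, -0.043 summed per best match, 0.12 without siblings, 0.15 spanned at least 50%, 0.15 with a Rhodopseudomonas nucleotide match, 0.15 with 5 fragments added and 0.082 by KEGG description. The tricarboxylic acid cycle stood at -0.42 (percentile 3.04) with a minimum of 1 fragment and -0.077 by KEGG description, both within, and was 0.70 over all mapped reads, 0.36 when spanned at least 50% and 0.93 summed. Oxidative stress defence was 0.49 with a minimum of 200 fragments, 0.52 with a Rhodopseudomonas nucleotide match, -0.47 (percentile 3.36, within) over all mapped reads and -1.01 when spanned at least 50%. Nitrogen fixation lay beyond at -0.69 with a minimum of 50 fragments and -0.71 at 500 bases or more, TonB-dependent receptors at 0.27 over all mapped reads, and, when spanned at least 50%, chaperones and proteases at -0.77 and fatty acid oxidation at -0.93.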

Other observations

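Within the other genera, each scaled on its own unigenes, 6 of 23 gene lists of Clostridium unigenes and 5 of 23 of Rhodovulum unigenes lay beyond the matched random lists. These ratios were chosen after seeing the data, and each genus may hold several species. Among Clostridium unigenes, 29 of oxidative stress defence had a median log2 ratio of 1.24 (percentile 99.995), 17 of them at least 2-fold higher and 4 at least 2-fold lower. The Calvin cycle list, whose words also match enzymes shared with other routes such as transketolase, had a median of 1.59 over 6 unigenes (percentile 98.8). Lower were glycoside hydrolases, 23 unigenes, with a median of -0.78 (percentile 0.28), two-component systems, 41 unigenes, -0.67 (percentile 0.575), ATP synthase, 9 unigenes, -0.95 (percentile 0.92), and hydrogenase, 10 unigenes, -0.78 (percentile 1.99). The Clostridium unigenes with most fragments were alpha,alpha-phosphotrehalase, Unigene2181_All, with 12150 and 5055, aminoglycoside phosphotransferase, CL214.Contig1_All, with 4184 and 4429, and 4-alpha-glucanotransferase, Unigene1471_All, with 5999 and 2031.

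Among Rhodovulum unigenes, bacteriochlorophyll and carotenoid synthesis (29 unigenes) had a median of -0.44 at percentile 0.305 beyond the lower share of the genus, and chaperones and proteases (55 unigenes) a median of -0.32 at percentile 0.5. Oxidative stress defence (28 unigenes) stood at -0.35 (percentile 2.32), the Calvin cycle (13 unigenes) at -0.51 (percentile 1.73), and cell division and envelope (24 unigenes) at 0.40 (percentile 99.5). Lists of Massilia unigenes are not given, since 341 of 610 held no fragment in 1 library. The most abundant Massilia unigene with a named function was alkyl hydroperoxide reductase subunit F, CL19.Contig1_All, with 34 control and 927 treated fragments. The unigenes named in these genera were chosen after their values were seen.

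A hypothesis from the Rhodopseudomonas values is that enzymes of the glyoxylate and methylcitrate routes were higher together after the treatment. Shared reads are argued against as its source, since the median of isocitrate lyase, methylcitrate synthase and 2-methylcitrate dehydratase was 1.87 over all mapped reads. Massilia sequence is argued against as well. The nucleotide match of all 3 lay in Rhodopseudomonas, against 1 of 610 Massilia unigenes. The 37117 treated fragments of isocitrate lyase compare with at most 1168 on any Massilia unigene. The highest log2 ratio of the 3 by library total was 2.42 (upper limit of the 95% interval 2.76). It lay under the lower quartile of 5.14 over the 101 Massilia unigenes that also held at least 100 fragments, with counts under 3 set to 3. Of these 101, 3 lay at or under 2.42. For Massilia unigenes near 0 in the control, that minimum and the count of 3 fix how low the ratio can be, so this comparison does not decide by itself. Earlier versions of this test over all 610 Massilia unigenes, with a quartile of 4.37 and of 2.15 with counts under 3 set to 3, were set by counts of 0 and decide nothing. All these tests were chosen after the values were seen. Enzymes not examined before (malate synthase, methylisocitrate lyase, propionyl-CoA carboxylase, methylmalonyl-CoA mutase and phosphoenolpyruvate carboxykinase) were predicted beforehand to have a median of at least 0.5 if the routes rose together and under 0.25 if not. They had a median of 0.28 over 10 unigenes, from -0.36 to 0.63, with 7 above 0, which decides neither way. Most were named propionyl-CoA carboxylase, methylmalonyl-CoA mutase or phosphoenolpyruvate carboxykinase, which belong to neither route, so that this median could not decide the hypothesis. Of the routes themselves, the malate synthase unigene stood at 0.63 and the methylisocitrate lyase unigene, named by its Swiss-Prot match only, at 0.30. 1 of the 10, CL123.Contig1_All, had been seen before under another name, a histidine kinase. The first search had also taken in 2-isopropylmalate synthase, a different enzyme, and gave 0.30 over 13 unigenes, and the search was corrected after that value was seen.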
